A study of Mus musculus with 2 samples.

How the data were processed

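Cells of mouse skeletal muscle were measured in 1 library labelled wild type and 1 library labelled as an endothelial Glut1 knockout. Per the labels' protocols, muscle was digested with dispase and collagenase for 25 min at 37 °C. Calcein-positive CD45+CD31- and CD31+CD45- cells were then sorted and loaded on a 10x Chromium 3' v3.1 kit with 10000 cells aimed, per the same protocols. The files hold 9655 barcodes in the library labelled wild type and 11756 in the library labelled knockout. This sort sets the ratio of immune to endothelial cells. It did not leave out every cell of neither kind, since clusters named stromal (84 and 87 cells) and glial (26 and 18 cells) were found. The protocols call the cells human in 1 place, but all 43699 gene identifiers in the files are mouse identifiers.

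The deposited values are UMI counts per gene and barcode, with no normalization. The matrices were written by Cell Ranger 7.1.0, per the file headers, while the submitters' processing notes name Cell Ranger 5.0.0 and a build written as GRCm39.p6. The annotation at hand follows an earlier mouse build than the one named, so no coordinates are given and genes are identified by symbol and Ensembl identifier. Counts of the 124 symbols that occur more than once were kept apart by identifier. The deposited barcodes had already been selected, since the lowest held 500 UMIs in each library.

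Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 488 barcodes from the library labelled wild type and 323 from the library labelled knockout. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected rate of 0.08. The 258 (2.81%) and 438 (3.83%) called doublets were removed, which left 8909 and 10995 cells. Counts were log-normalised to 10000 per cell. The 3000 most variable genes gave 30 principal components and a graph of 15 neighbours, which was clustered by the Leiden method at resolution 1 with seed 0 and without integration of the libraries. Tools were Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.

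The 30 clusters were named by markers that were fixed before the data were examined. The scoring rule was settled after the clusters had been seen, so names are a choice made with knowledge of the data. A marker counted for a cluster at 2 times or more its level elsewhere and at least 20 CPM, in at least 10% of cells and 1.5 times the share elsewhere; at least 3 markers were needed. A cluster in which an unrelated class also reached 60% of its markers was left unnamed as mixed. Also left unnamed was one with a median depth under 1/3 of the library's and no marker among its top 10 genes. The same held for a cluster with more markers of another class among its top 10 genes. This gave 9 classes, of which 8 were compared, since glial cells were too few. The stromal class is a cluster of mural cells with fibroblast markers. Low-UMI endothelial clusters, 12.5% of cells in the library labelled wild type and 9.64% in the library labelled knockout, were left unnamed, and unnamed immune clusters held 10.4% and 11.6%. Endothelial-like cells were clustered again alone for their subtypes. Subclusters that the rule left unnamed were called capillary by a looser rule. It asked for at least 3 capillary markers at 2 times or more their level in the named subclusters. These markers needed at least 20 CPM and 10% of cells, without the limit of 1.5 times the share elsewhere. No marker of neutrophils, macrophages, monocytes, T cells or B cells could be among the top 10 genes.

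UMIs were summed per class and library and scaled by all UMIs of the class and library to CPM. Levels have exact Poisson 95% intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals; with 1 library per group none of them holds the variation between animals, and no test between groups was made. The endothelial-like cells held 6649153 and 8632819 UMIs (library labelled wild type first), at median depths of 3467.5 and 3151.5 UMIs per cell, and the macrophage-like cells 11877117 and 4792244 UMIs. A list's median log2 ratio is that of its members with at least 20 UMIs, with a pseudocount of 5 CPM in the median and the ranking, an interval from 1000 simulated draws and a percentile among 10000 random lists of the same size matched in 20 bins of level. For shares of cells with a gene, each cell was thinned to 2000 UMIs and cells with fewer were left out. Carry-over of macrophage RNA into endothelial-like cells was the mean ratio of the levels of C1qa, C1qb and C1qc in endothelial-like over macrophage-like cells, 0.714% in the library labelled wild type and 0.278% in the library labelled knockout.

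Genes named in the text followed a rule fixed before the data were examined. They are Slc2a1, Spp1, the 4 members with the log2 ratios farthest from 0 of each list in the outer 5% of random lists, the 2 members with most UMIs of each other list, and the 12 highest and 12 lowest ranked genes of endothelial-like and macrophage-like cells; a few genes that the rule takes are not given in the text. Ranked genes had at least 30 CPM in 1 library, at least 100 UMIs in all, and at least 20% of the level of the highest other class of at least 100 cells. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, Xist, Y-linked and unnamed genes and markers of other classes were not ranked. For other classes the same ranking gave 5 genes each way, a step added after seeing the data. Of the fixed hypoxia genes, Ero1l was not found under that symbol.

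The steps were tested on simulated counts, drawn as independent Poisson counts from the summed endothelial-like cells of both libraries. Such counts hold no spread between cells. Coverage near 95% was therefore built in, and it checks the calculation and not whether the intervals fit real cells. For single genes, 9967 were simulated, and the 95% interval held the true ratio in 95.4% of 9771 unchanged genes and excluded 1 in 4.59% of them. Among changed genes it excluded 1 for 100% at folds of 2 and 0.5, 94% at a fold of 1.5 and 91.8% at a fold of 0.67. Among 13893 simulated genes, 6.5% of 200 unchanged lists and 100% of lists changed by 1.5 lay in the outer 5%. Among 5412 genes, all 12 ranked higher and all 12 ranked lower had been planted in that direction. More genes were planted than ranked, so this does not measure how many planted genes were found.

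Alternatives fixed before the data were examined were TMM factors, the mean of per-cell levels, thinning to 2000 UMIs (or 1000 for shares), a pseudocount of 1 CPM for the ranking, no minimum for list members, a filter of at least 1000 genes and at most 5% mitochondrial UMIs, no filter, called doublets kept, Leiden resolutions of 0.5 and 2, and scaling of genes within each library. Those chosen after seeing the data were equal cluster weights over clusters of at least 50 cells in each library (also the limit for list medians and ratios by cluster), addition of the low-UMI endothelial clusters, and other denominators for the macrophage share. TMM factors shifted log2 ratios by −0.10 in macrophage-like and by 0.03 in endothelial-like cells. The closing part gives the values of the main results that moved beyond their interval, and counts for the rest.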

Results

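Single-cell RNA was measured by droplet 3' sequencing in cells sorted from mouse skeletal muscle, from animals labelled wild type and from animals labelled as lacking Glut1 in the endothelium. Glut1 is the glucose transporter encoded by Slc2a1. Each genotype was 1 library, so no difference given here has a replicate check, and each value describes these 2 libraries and not the genotypes. The library labelled wild type held 9655 barcodes and 87995131 UMIs, with a median of 5802 UMIs per barcode. The library labelled knockout held 11756 barcodes and 90368236 UMIs, with a median of 4743. After filtering, 8909 and 10995 cells were used. All intervals are 95% intervals that cover counting error only, and ratios are those of the library labelled knockout over the library labelled wild type, with levels in CPM, the UMIs of a gene scaled by all UMIs of the class.

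The first question was whether the deleted gene was lower in the endothelium. Slc2a1 (ENSMUSG00000028645) was not lower in the endothelial-like cells of the library labelled knockout. Its level there was 43.0 CPM (38.7 to 47.6; 371 UMIs), against 31.9 CPM (27.7 to 36.5; 212 UMIs) in the library labelled wild type, a ratio of 1.35 (1.14 to 1.60). By endothelial subtype the ratio was 1.97 (1.45 to 2.71) in capillary, 1.13 (0.792 to 1.63) in arterial and 0.883 (0.655 to 1.20) in venous cells. Within endothelial clusters 9, 10, 14 and 15 it was 1.44 (0.889 to 2.34), 0.966 (0.726 to 1.29), 1.09 (0.723 to 1.66) and 1.01 (0.704 to 1.49). Each of these intervals includes 1, so no rise of Slc2a1 was detectable within a cluster. The clusters were formed without integration and partly follow the library. Cluster 9 held 923 and 551 cells and cluster 15 held 284 and 1217 (library labelled wild type first). Part of a difference between libraries may therefore lie between clusters, and the values within them cannot exclude a rise. Macrophage-like cells stood at 25.2 CPM in the library labelled knockout against 41.1 CPM, and neutrophil-like cells at 76.6 against 119 CPM. The counted 3' tag may lie outside the deleted part, in which case it checks nothing, and the deleted exons were not given in the labels. Slc2a1 therefore does not check which library is the knockout, and every direction below is between libraries as they are labelled. With each endothelial cluster given the same weight in both libraries, a setting chosen after seeing the data, the log2 ratio was 0.08 in place of 0.43. That setting rests on the same clusters and shares their limit.

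**Figure D1:**
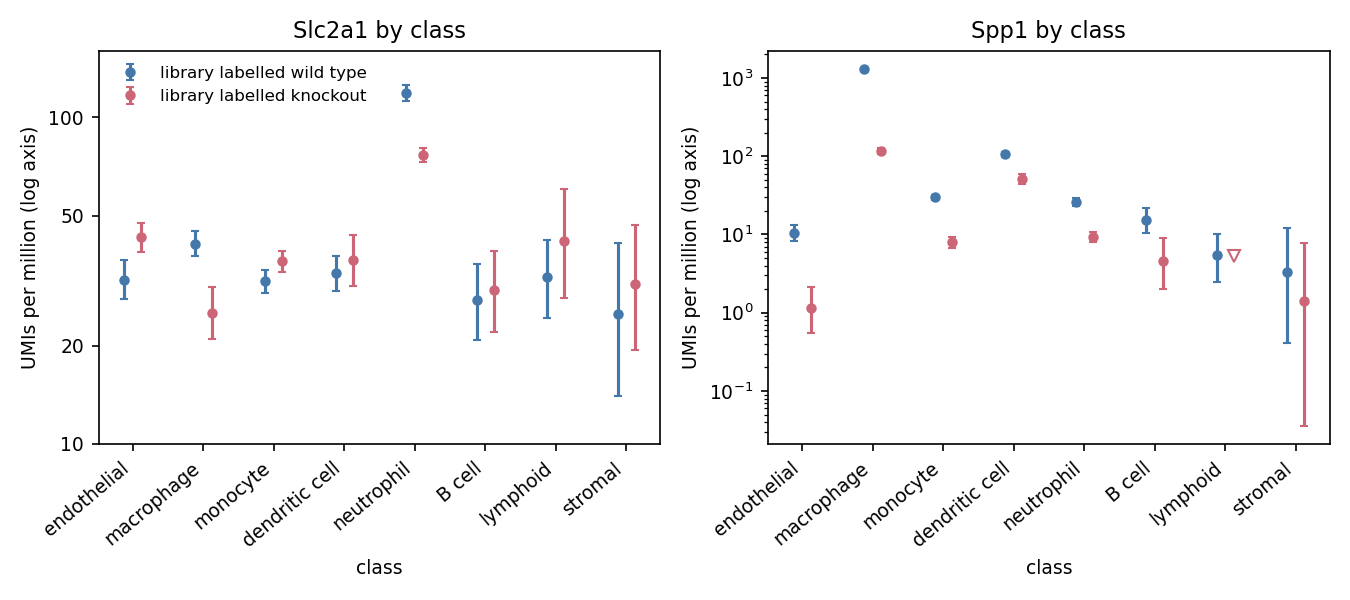
Levels of Slc2a1 and Spp1 in CPM (log axis) in each cell class of the library labelled wild type and the library labelled knockout; points are the summed UMIs of the class and bars are exact Poisson 95% intervals. Slc2a1 in endothelial-like cells is 31.9 CPM in the library labelled wild type and 43.0 CPM in the library labelled knockout, and Spp1 in macrophage-like cells is 1295 and 117 CPM.

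Spp1 (ENSMUSG00000029304), which encodes osteopontin, a secreted phosphoprotein that binds integrins and CD44, was asked of the endothelial-like cells next. It was scarce there and lower in the library labelled knockout, at 1.16 CPM (0.555 to 2.13; 10 UMIs) against 10.5 CPM (8.21 to 13.3; 70 UMIs), a ratio of 0.110 (0.0506 to 0.215). Lymphatic cells held 48 of the 70 UMIs in the library labelled wild type, in 3 of 42 cells, and 7 of the 10 in the library labelled knockout, in 2 of 33 cells. In capillary cells Spp1 stood at 0.204 CPM (1 UMI) against 3.92 CPM (2.19 to 6.47; 15 UMIs). Macrophage-like cells held far more Spp1, 117 CPM in the library labelled knockout and 1295 CPM in the library labelled wild type. Carry-over of macrophage RNA, measured by C1qa, C1qb and C1qc, would by itself give endothelial-like cells 9.25 CPM of Spp1 in the library labelled wild type and 0.326 CPM in the library labelled knockout. Capillary cells would receive 4.70 and 0.221 CPM in the same order, so that Spp1 in capillary cells was not distinguishable from carry-over at this depth. The class estimate did not hold in other parts of the library labelled wild type. Lymphatic cells would receive 5.60 CPM, against 219 CPM (161 to 290) observed. All endothelial-like cells but the lymphatic would receive 9.37 CPM, against 3.42 CPM (2.14 to 5.18) observed. With called doublets kept, the log2 ratio in endothelial-like cells was −1.71 in place of −3.18.

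The next question was which metabolic and signalling programmes differed in the endothelial-like cells, with 15 gene lists fixed before the data were examined. Immediate early genes, the hypoxia list and endothelial activation stood higher in the library labelled knockout. MHC class II genes, glycolysis and the interferon response stood lower, the interferon list having a median of 0.06 where clusters were given the same weight. Within the glycolysis list Pfkfb3, which makes the activator of phosphofructokinase, went the other way at 2.05-fold higher. The medians of 6 of the 15 lists lay in the outer 5% of 10000 random lists matched on expression, a description of these libraries. Cluster 9 held 55.7% of the endothelial-like cells in the library labelled wild type and cluster 15 held 53.5% in the library labelled knockout, so values by cluster are given beside the lists. Where clusters follow the library in this way, values by cluster may miss part of a difference. These values are for clusters with at least 50 cells in each library, which leaves out the lymphatic cluster 25, with 42 and 33 cells.

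Of the 14 genes of the dissociation stress list, 10 were higher in the library labelled knockout, with a median log2 ratio of 0.63 (0.60 to 0.66; percentile 100). The transcription factors Junb, Egr1 and Fosb were higher by 2.02 (1.96 to 2.08), 1.92 (1.86 to 1.99) and 1.79 (1.67 to 1.92) fold, and Zfp36, which destabilises cytokine messages, by 1.85 (1.79 to 1.91) fold. The list was higher in each of the 4 endothelial clusters compared. In other classes the median was 0.27 in stromal, 0.23 in B-like, 0.18 in dendritic-like, 0.12 in monocyte-like and 0.07 in neutrophil-like cells, and −0.46 in lymphoid cells. In neutrophil-like cells matched random lists had a median of 0.20, so 0.07 lay at percentile 11.2 and was not high for that class. Within clusters the stress median was −0.49 in the B-like cluster 1. The neutrophil-like clusters were split, at −0.47, −0.51, −0.04 and 0.46 in clusters 0, 2, 3 and 4. In the monocyte-like clusters 5, 6 and 27 it was −0.10, 0.25 and 0.05. Hypoxia genes were higher for 10 of 11 measured members, with a median of 0.36 (0.20 to 0.50; percentile 99.99). Bnip3, a mitophagy receptor, was higher by 2.07 (1.79 to 2.41) fold and Vegfa, the vascular growth factor, by 1.86 (1.29 to 2.70) fold. Ankrd37, a target of hypoxia-inducible factor, stood at 1.71 (1.32 to 2.24) fold and Ddit4, an inhibitor of mTORC1, at 1.52 (1.43 to 1.62) fold. In cluster 15 the hypoxia median was −0.02, against values above 0 in the other 3 clusters.

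Endothelial activation genes had a median of 0.39 (0.18 to 0.41; percentile 100), with 8 of 11 members higher in the library labelled knockout. Cxcl10, a chemokine for T cells, was higher by 4.45 (2.68 to 7.80) fold, and the leukocyte adhesion molecules Icam1 and Sele by 1.63 (1.44 to 1.85) and 1.40 (1.16 to 1.70) fold. Ccl2, the monocyte chemokine, went the other way, 3.70-fold lower (2.89 to 4.78), at 10.1 CPM against 37.3 CPM. The activation median was −0.13 in cluster 15 and above 0 in the other 3 clusters. It was 0.16 (−0.12 to 0.36) in cluster 9, 0.27 (0.13 to 0.41) in cluster 10 and 0.08 (−0.33 to 0.45) in cluster 14, the last from 4 measured members. Each of these lies below the 0.39 of all endothelial-like cells.

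MHC class II genes were lower in the library labelled knockout for 6 of 6 measured members, with a median of −0.67 (−0.82 to −0.51; percentile 0). Cd74, the invariant chain, was 2.11-fold lower (1.79 to 2.49), and the class II chains H2-Eb1, H2-Ab1 and H2-Aa were 2.04, 1.97 and 1.68-fold lower. Macrophage RNA would by carry-over alone supply 61.9% of endothelial Cd74 in the library labelled wild type and 41.5% in the library labelled knockout. These shares rest on the class estimate that did not hold for Spp1 in parts of the endothelial-like cells, so they are uncertain. By cluster the median was −1.26 in cluster 9 and −1.32 in cluster 15, but 0.40 in cluster 10 and 0.44 in cluster 14.

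Glycolysis genes were lower for 14 of 17 measured members, by a small amount, with a median of −0.18 (−0.23 to −0.08; percentile 0.46). Eno1, or enolase, was 1.30-fold lower (1.03 to 1.63), and the lactate transporter Slc16a1 1.36-fold lower (0.993 to 1.87). Pfkfb3 stood at 88.3 CPM in the library labelled knockout and 43.0 CPM in the library labelled wild type, and Gpi1, the glucose phosphate isomerase, was higher by 1.25 (1.13 to 1.40) fold. The glycolysis median was 0.17 in cluster 15 and below 0 in the other 3 clusters, and was −0.04 under the stricter cell filter. Interferon response genes had a median of −0.19 (−0.26 to −0.09; percentile 0.46), with 9 of 14 lower. The interferon-induced genes Ifi44, Ifit2 and Oasl2 were 1.42, 1.41 and 1.33-fold lower, and the antiviral gene Rsad2 was higher by 1.35 (1.22 to 1.48) fold. Within clusters the interferon median took the other direction in 3 of 4, at 0.09 in cluster 9, 0.14 in cluster 10, −0.08 in cluster 14 and 0.22 (0.03 to 0.35) in cluster 15.

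The other 9 endothelial lists lay within the inner 95% of random lists. Glucose transporters had a median of 0.11 (−0.07 to 0.31; percentile 81.6) and Slc2a3, or Glut3, a ratio of 1.09 (0.781 to 1.54). Genes of the ATF4 amino acid response had a median of 0.17 (−0.10 to 0.30; percentile 97.49), just inside that bound; Slc3a2, the heavy chain of amino acid transporters, was higher by 1.41 (1.33 to 1.49) fold and Atf4 by 1.36 (1.24 to 1.505) fold. Serine and one-carbon genes had a median of −0.01, with Slc1a5 at 1.09 and Mthfd1l at 1.06. Pentose phosphate genes had a median of 0.02, with Taldo1 at 0.901 and Pgls at 0.733. TCA cycle and respiratory chain genes had a median of −0.11 (percentile 8.74), with Cox4i1 at 0.948 and Ndufa4 at 0.820. Fatty acid handling genes had a median of −0.11 (percentile 5.81), and its most abundant members were close to equal, with the lipid chaperone Fabp4 at 0.957 and the fatty acid receptor Cd36 at 1.17. Angiocrine genes had a median of −0.05, with Cxcl12 at 0.775, which leads cluster 9, and Kitl at 1.001. Tip cell genes had a median of −0.09, with Plvap at 0.987 and Dll4 at 1.14, and cell cycle genes had a median of −0.08, with Pcna and Mcm6 both at 1.04.

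**Figure D2:**
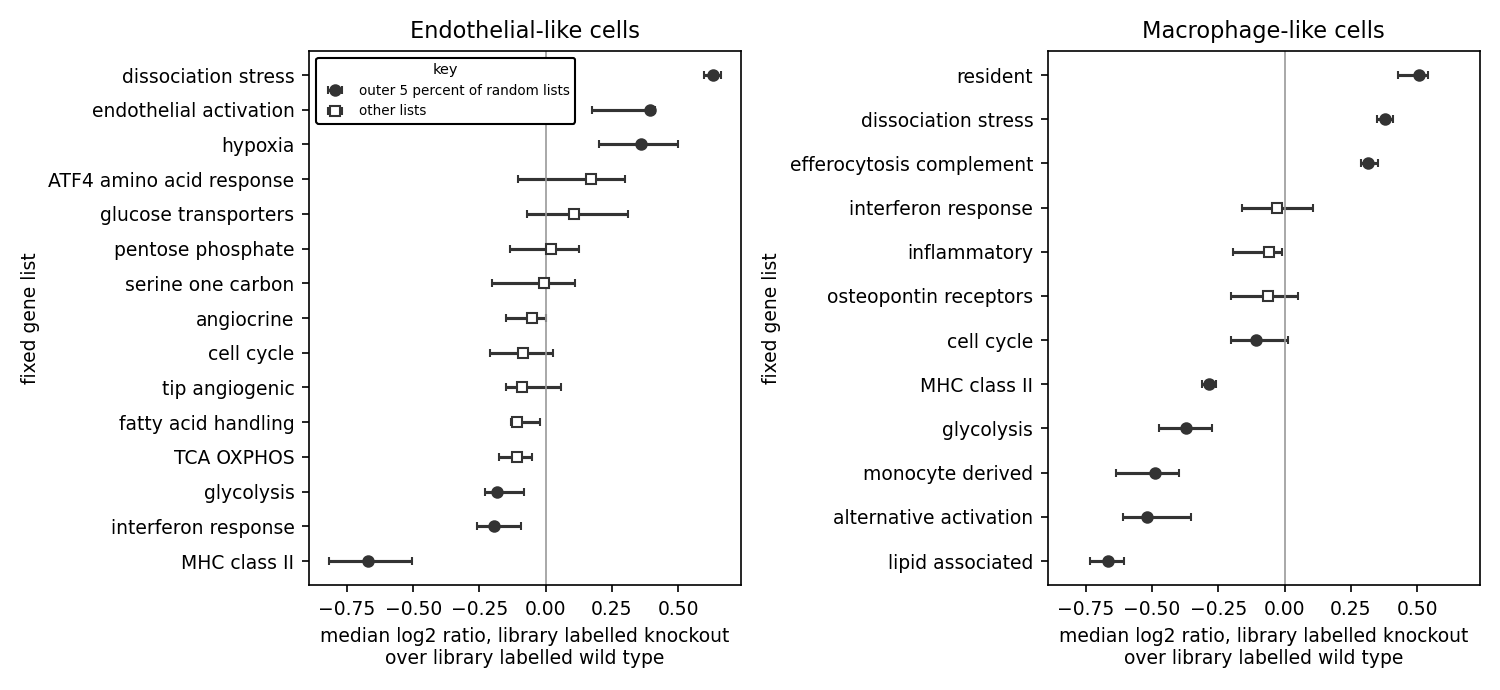
Median log2 ratio (library labelled knockout over library labelled wild type) of each fixed gene list in endothelial-like and macrophage-like cells; bars are 95% intervals for counting error and filled circles are lists in the outer 5% of random lists. Stress genes are highest in endothelial-like cells at 0.63, and lipid-associated genes are lowest in macrophage-like cells at −0.67.

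Single genes were then ranked in the endothelial-like cells, among 5256 eligible genes. In the library labelled knockout, Cbx7 (ENSMUSG00000053411), a Polycomb subunit, was higher by 2.63 (2.24 to 3.104) fold, and Per2, a repressor in the circadian clock, by 2.60 (2.01 to 3.39) fold. Spock2, an extracellular proteoglycan, was higher by 2.54 (2.23 to 2.90) fold, Map3k6, a MAP kinase kinase kinase, by 2.35 (1.98 to 2.80) fold, and Pik3ip1, an inhibitor of PI3 kinase, by 2.13 (1.90 to 2.40) fold. Ier3, an immediate early gene, stood at 579 CPM against 251 CPM, a ratio of 2.30 (2.18 to 2.44). The interferon regulatory factor Irf1, the cold-inducible RNA-binding protein gene Cirbp, the cytokine signalling suppressor Socs3, the Notch target Hes1 and Ier5l stood between 2.04 and 2.08 fold. Junb (ENSMUSG00000052837) was the most abundant of the 12, at 1945 CPM against 964 CPM. Within clusters 9, 10, 14 and 15 the ratio was 1.54, 1.975, 1.88 and 1.02 for Map3k6, 1.21, 2.13, 1.405 and 1.16 for Pik3ip1, and 1.51, 1.44, 2.47 and 1.25 for Per2. In the same clusters it was 1.46, 2.10, 3.30 and 1.38 for Cbx7 and 3.83, 1.22, 1.74 and 1.21 for Junb. Cbx7 was also higher in neutrophil-like cells, at a ratio of 3.69, and in monocyte-like (3.13), macrophage-like (2.87) and B-like (2.73) cells. In dendritic-like cells its ratio was 0.955 (0.445 to 1.92), and the lymphoid and stromal intervals also include 1.

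At the other end of the ranking, Efna5, an ephrin ligand, was 4.44-fold lower (3.64 to 5.45) in the library labelled knockout, at 14.8 CPM against 65.9 CPM. Rbp7, a retinol-binding protein, was 3.40-fold lower (3.24 to 3.57), at 271 CPM against 924 CPM. Rbp7 leads cluster 9, and within clusters 9, 10, 14 and 15 its ratio was 0.452, 0.843, 0.326 and 0.335. Ccl21a, a lymphatic chemokine, and Nts, or neurotensin, lead the lymphatic cluster 25, which held 42 and 33 cells, and were 3.90 and 3.74-fold lower. Ccl21a has near-identical copies, so its value is uncertain. Gkn3, a gastrokine, was 3.02-fold lower (2.45 to 3.73). The Slit receptor Robo2 and Srgap1, a GTPase-activating protein of the Slit-Robo pathway, were 2.24 and 2.10-fold lower. Nhs, an actin regulator, was 2.38-fold lower, Apba1, an adaptor, 2.19-fold, Mmd 2.11-fold, the intermediate filament gene Nes 2.03-fold and Ccnd1, or cyclin D1, 1.98-fold. Within cluster 9 the ratios were nearer 1, at 0.711 for Nes, 0.761 for Ccnd1, 0.767 for Robo2 and 0.695 for Mmd. In cluster 15 that of Ccnd1 was 1.76 (0.873 to 4.01). Cluster 14, with 14.3% of the endothelial-like cells in the library labelled wild type and 9.19% in the library labelled knockout, held 429 and 113 Efna5 UMIs, a ratio of 0.283. In each of the 4 endothelial clusters compared, which leaves out cluster 25, the direction was the same for 10 of the 12 higher genes and 5 of the 12 lower genes. Some of these directions are within counting error. In cluster 15, for example, the ratio was 1.25 (0.875 to 1.84) for Per2, 1.02 (0.807 to 1.30) for Map3k6 and 0.882 (0.581 to 1.38) for Nes. Socs3 and Spock2 were lower in 1 cluster, and Ccl21a, Gkn3, Robo2, Mmd and Ccnd1 were not lower in all 4. Efna5 had no UMIs in cluster 10 and Nts none in cluster 14, so these 2 genes had no direction there.

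The makeup of the immune-like cells was compared next. Macrophage-like cells were a smaller share of the immune-like cells in the library labelled knockout, 9.72% (9.003 to 10.5; 611 of 6283 cells) against 25.1% (23.9 to 26.3; 1278 of 5100 cells). Neutrophil-like cells were a larger share, 61.4% (60.2 to 62.6) against 34.1% (32.8 to 35.4). Dendritic-like cells were 4.07% (3.60 to 4.59) against 12% (11.1 to 12.9), and monocyte-like cells 20.4% (19.4 to 21.4) against 22.4% (21.3 to 23.6). Lymphoid cells, a cluster with T, NK and ILC2 markers, were 1.59% (1.30 to 1.93) against 3.73% (3.22 to 4.28), and B-like cells 2.82% (2.42 to 3.26) against 2.69% (2.26 to 3.17). The 2 B-like clusters went apart: cluster 1 was 2.37% (149 cells) against 1.22% (62 cells), and cluster 22 was 0.446% (28 cells) against 1.47% (75 cells). Shares of 1 whole move together: without neutrophil-like cells, a denominator chosen after seeing the data, macrophage-like cells were 25.2% against 38.0%, and among macrophage-like and dendritic-like cells alone they were 70.5% against 67.6%. The sort of CD45+CD31- and CD31+CD45- cells sets the ratio of immune to endothelial cells, so the endothelial share of all cells, 20.7% against 18.6%, is not a measure of the tissue. Clusters with genes of developing blood cells were present in both libraries, and the labels do not say whether marrow was part of the tissue, so the immune shares are not known to be those of muscle alone. Clusters left unnamed held 21.2% of cells in the library labelled knockout and 22.9% in the library labelled wild type.

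**Figure D3:**
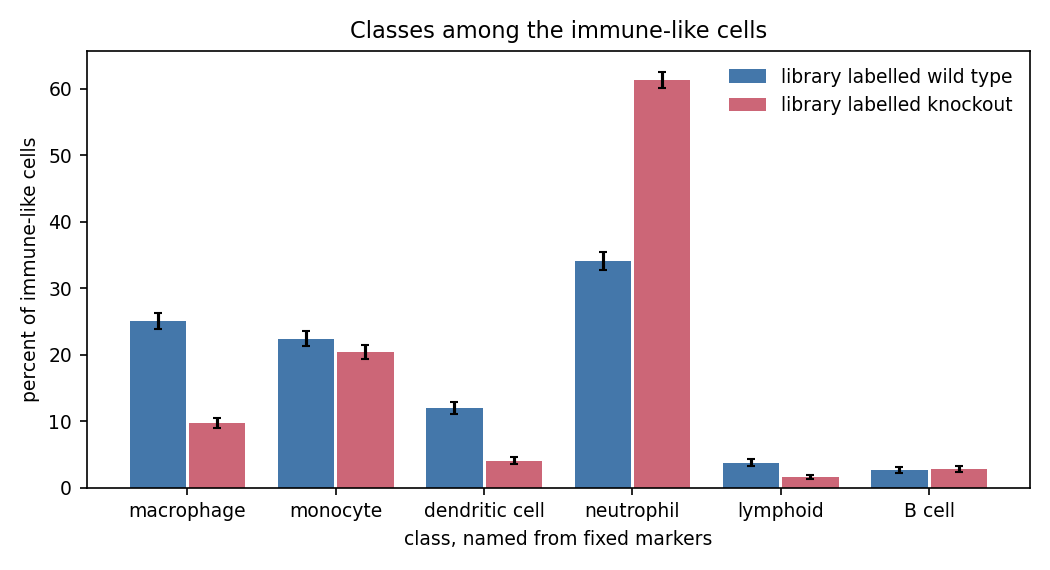
Share of the immune-like cells (percent, axis from 0) taken by each immune class in the library labelled wild type and the library labelled knockout, with exact Clopper-Pearson 95% intervals as error bars. In the library labelled wild type macrophage-like cells are 25.1% and neutrophil-like cells 34.1%, and in the library labelled knockout 9.72% and 61.4%.

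Endothelial subtypes were compared in the endothelial-like cells clustered alone. Capillary cells were 63.6% (61.6 to 65.6) in the library labelled knockout and 65.6% (63.3 to 67.9) in the library labelled wild type. Arterial cells were 20.6% (19.0 to 22.3) against 16% (14.3 to 17.9), venous cells 10.3% (9.07 to 11.6) against 8.57% (7.27 to 10.0) and lymphatic cells 1.45% (1.0 to 2.03) against 2.54% (1.83 to 3.41). Subclusters without a name held 4.00% against 7.25%. The arterial difference, knockout-labelled minus wild-type-labelled library, of 4.62 points took the opposite sign without the cell filter, at −2.43 points, and with genes scaled within each library, at −0.97 points. The capillary difference of −2.01 points was 6.15 points under the stricter cell filter and 3.87 points without the cell filter.

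In the macrophage-like cells 12 lists were compared, to see which programmes differed beside the endothelium. Genes of resident macrophages, efferocytosis and complement stood higher in the library labelled knockout, together with immediate early genes. Genes of lipid-associated, alternatively activated and monocyte-derived macrophages, of glycolysis and of MHC class II stood lower, the MHC class II list having a median of 0.14 where clusters were given the same weight. Spp1 was 11.02-fold lower (10.1 to 12.01) and Arg1, or arginase, 55.9-fold lower (28.3 to 129.9). The medians of 9 of the 12 lists lay in the outer 5% of random lists. Cluster 11 held 58.1% of the macrophage-like cells in the library labelled wild type and 41.2% in the library labelled knockout, and cluster 20 held 22.7% and 37.8%.

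Resident macrophage genes were higher for 15 of 16 members, with a median of 0.51 (0.43 to 0.54; percentile 100). Vsig4 (ENSMUSG00000044206), a complement receptor, was higher by 2.69 (2.38 to 3.03) fold and Lyve1 (ENSMUSG00000030787), a hyaluronan receptor, by 2.30 (2.19 to 2.43) fold, at 578 CPM against 251 CPM. The haemoglobin scavenger receptor Cd163 and the lectin Fcna were higher by 1.71 (1.61 to 1.82) and 1.67 (1.37 to 2.02) fold. Lyve1 leads cluster 20, and with the same cluster weights the median was 0.04; it was 0.37 in cluster 11, −0.17 in cluster 20 and −0.44 in cluster 23. With every cell thinned to 2000 UMIs, 33.7% (29.8 to 37.7) of macrophage-like cells held Lyve1 in the library labelled knockout and 19.0% (16.8 to 21.3) in the library labelled wild type. The unthinned shares were 41.7% and 23.9%, at median depths of 6699 and 8070.5 UMIs. Neutrophil-like cells, which should lack Lyve1, gave 0.160% and 0.351% after thinning and had median depths of 4247 and 5464 UMIs. Thinning left out 44 and 108 macrophage-like and 115 and 31 neutrophil-like cells.

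Lipid-associated genes were lower for 11 of 12 members, with a median of −0.67 (−0.73 to −0.61; percentile 0), and the median was below 0 in 3 of 3 clusters. Gpnmb, a glycoprotein of lipid-laden macrophages, was 7.59-fold lower (5.72 to 10.3), the lipid chaperone Fabp5 3.96-fold (3.70 to 4.24) and Ctsd, or cathepsin D, 2.36-fold (2.22 to 2.51). Spp1 leads cluster 11, where its ratio was 0.135 (0.124 to 0.147), at 248.5 CPM in the library labelled knockout and 1839 CPM in the library labelled wild type; it was 0.976 (0.598 to 1.58) in cluster 20. After thinning, 5.29% (3.60 to 7.47) of macrophage-like cells held Spp1 in the library labelled knockout against 20.5% (18.2 to 22.9), with 10.1% and 30.8% unthinned, and 1.28% and 3.45% in thinned neutrophil-like cells.

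Alternative activation genes had a median of −0.52 (−0.61 to −0.35; percentile 0), with 11 of 14 lower. Arg1 (ENSMUSG00000019987) stood at 1.67 CPM (8 UMIs) in the library labelled knockout and 93.4 CPM (1109 UMIs) in the library labelled wild type. The chemokine gene Ccl8 was 2.66-fold lower (2.44 to 2.89) and the lectin gene Cd209g 2.97-fold (2.03 to 4.47), the latter uncertain because its family has near-identical members. Klf4, a transcription factor, was higher by 1.84 (1.76 to 1.93) fold. The median was 0.25 in cluster 11, −1.06 in cluster 20 and −0.21 in cluster 23. Monocyte-derived genes had a median of −0.49 (−0.63 to −0.40; percentile 0), with 8 of 10 lower, and were lower in 3 of 3 clusters. The matrix genes Thbs1, Fn1 and Vcan were 2.22 (2.09 to 2.35), 2.08 (1.98 to 2.19) and 1.86 (1.58 to 2.19) fold lower and Ms4a4c 2.01-fold (1.63 to 2.505).

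Glycolysis genes of the macrophage-like cells were lower for 13 of 16 members, with a median of −0.37 (−0.47 to −0.27; percentile 0). The glycolytic enzymes Pgk1, Pgam1, Pkm and Gapdh were 1.96, 1.86, 1.62 and 1.55-fold lower, and the median was −0.62 in cluster 11 but 0.02 and 0.03 in clusters 20 and 23. MHC class II genes were lower for 7 of 7 members, with a median of −0.28 (−0.31 to −0.26; percentile 0.76). Ciita, the class II transactivator, was 1.88-fold lower (1.52 to 2.33), H2-DMb1 1.30-fold, and Cd74 and H2-Ab1 1.22-fold. By cluster the class II median was 0.29 in cluster 11, −0.72 in cluster 20 and −0.52 in cluster 23. Efferocytosis and complement genes had a median of 0.32 (0.29 to 0.35; percentile 99.7), with 8 of 10 higher. The bridging ligands Gas6 and Pros1 were higher by 1.51 (1.41 to 1.61) and 1.52 (1.37 to 1.68) fold and the scavenger receptor Cd36 by 1.36 (1.30 to 1.43) fold, while the cholesterol exporter Abca1 was 1.57-fold lower (1.48 to 1.67). The efferocytosis median was 0.37, 0.01 and −0.28 in clusters 11, 20 and 23.

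Stress genes were higher for 12 of 14 members, with a median of 0.38 (0.35 to 0.41; percentile 99.99), and in 3 of 3 clusters. The AP-1 genes Jund, Jun and Fosb were higher by 1.73, 1.70 and 1.57 fold and Egr1 by 1.69 fold. Inflammatory genes had a median of −0.06 (−0.20 to −0.01; percentile 25.7), with the chemokines Cxcl2 at 0.813 and Ccl4 at 1.28, but the median was above 0 in each of the 3 clusters, 0.07 to 0.53. Osteopontin receptor genes had a median of −0.06 (−0.20 to 0.05; percentile 20.6), with Cd44 at 1.14 (1.10 to 1.19) and Itgb1 at 1.03 (0.977 to 1.10). Interferon response genes had a median of −0.03 (−0.16 to 0.11; percentile 14.5), with Bst2 at 0.898.

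Ranking of single genes among 4762 eligible genes gave a different set in the macrophage-like cells. Highest in the library labelled knockout was Cacna1a, the pore subunit of the P/Q-type calcium channel, by 10.6 (9.03 to 12.5) fold, at 169 CPM against 16 CPM, and it was higher in 3 of 3 clusters. Neo1, or neogenin, was higher by 4.27 (3.31 to 5.54) fold and Rarb, a retinoic acid receptor, by 3.32 (2.76 to 4.01) fold. Fxyd2, a regulator of the sodium pump that leads cluster 20, was higher by 2.69 (2.55 to 2.84) fold, Tmod1, a tropomodulin, by 2.69 (2.29 to 3.17) fold, and Colec12, a scavenger collectin, by 2.65 (2.40 to 2.92) fold. Ifi202b was higher by 2.88 (2.29 to 3.63) fold, a value uncertain because of near-identical relatives. Rgs7bp, Cpne8 and Rasgrp3, a Ras exchange factor, stood between 2.31 and 2.47 fold. Within clusters 11, 20 and 23 the ratio of Fxyd2 was 1.06 (0.858 to 1.31), 1.52 and 1.075, and that of Rarb 2.10, 2.12 and 1.37. Vsig4 was also among the 12 highest, not all of which are named here. Of the 12, 11 were higher in each of the 3 clusters; Vsig4 was lower in cluster 23, at a ratio of 0.844 (0.451 to 1.53).

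Arg1 and Spp1 were the lowest of the ranked genes in the library labelled knockout. Vegfa was 8.66-fold lower (6.47 to 11.9), at 9.81 CPM against 85.0 CPM, and Nt5e, which encodes the ectonucleotidase CD73, 7.55-fold (5.23 to 11.3). Pdpn, or podoplanin, was 5.996-fold lower (4.82 to 7.55), Clec4n, or Dectin-2, 5.30-fold (4.61 to 6.11), the membrane protease Mmp14 4.70-fold (3.72 to 6.03), and Ptgs2, or COX-2, 4.06-fold (3.37 to 4.94). Mucl1 was 4.11-fold lower and Arhgap24, a GTPase-activating protein, 3.68-fold (3.16 to 4.30). Of the 12 lowest, Spp1, Fabp5, Mmp14, Mucl1 and Nt5e were lower in each of the 3 clusters. The other 7 were lower in 2 of 3. Several of these directions are within counting error, with intervals that include 1. In cluster 20, Spp1 had a ratio of 0.976 (0.598 to 1.58), Mmp14 7 and 2 UMIs and Nt5e 6 and 1 (library labelled wild type first). Mucl1 had 7 and 1 UMIs in cluster 11. In cluster 11, Arg1 had a ratio of 0.0213 (0.00781 to 0.0466).

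Cell cycle genes were compared last in the macrophage-like cells, as a measure of proliferation. Their median was −0.11 (−0.20 to 0.01; percentile 0.71), with 13 of 18 members lower, and it was 0.05 with cells thinned to 2000 UMIs and 0.09 without the cell filter. Cenpf and Birc5, genes of mitosis, were 1.78 (1.14 to 2.86) and 1.37 (0.997 to 1.90) fold lower, while Mcm6 and Mcm5, of the replicative helicase, were higher by 1.41 (1.14 to 1.74) and 1.31 (0.956 to 1.78) fold. After thinning, 6.70% (4.79 to 9.08; 38 of 567) of macrophage-like cells held at least 2 cell cycle genes in the library labelled knockout and 7.01% (5.61 to 8.63; 82 of 1170) in the library labelled wild type, a difference not detectable at this depth. Unthinned shares were 30.8% and 34.8%, and thinned neutrophil-like cells gave 0.882% and 1.05%. By cluster the median was 0.19 in cluster 11, −0.85 in cluster 20 and −0.09 in cluster 23.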

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

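Of the tests in this part, those of clock phase and of glucocorticoid level were set down before their values were seen; the other 6 tests, the size of 0.5 on the log2 scale used to pick genes of opposite direction, and the comparison of clusters were chosen after the result was seen.

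Genes named in the text stood in opposite directions in endothelial-like and macrophage-like cells, with intervals that exclude equality in both classes; the difference between the classes was not tested. Members of the hypoxia list were 4 of them: Bnip3 had a log2 ratio of 1.05 in endothelial-like and −0.53 in macrophage-like cells, Ddit4 0.61 and −0.94, Ankrd37 0.78 and −1.30, and Vegfa 0.89 and −3.11. Lyve1, which marks lymphatic endothelium and a resident macrophage cluster, had −0.52 and 1.20. Fxyd2 had −2.27 and 1.43, Rgs7bp −1.84 and 1.30, and Arhgap24 1.90 and −1.88. These last 3 were scarce in endothelial-like cells, at 7.82, 4.96 and 3.36 CPM at most, and Ankrd37 was scarce in macrophage-like cells, at 5.14 CPM at most.

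The first pattern weighed was that Slc2a1 was not lower in the endothelial-like cells of the library labelled knockout. Free RNA from neutrophil-like cells, where Slc2a1 stood at 119 and 76.6 CPM, is argued against: Slc2a1 stood at 26.2 and 35.1 times the level that the carry-over of S100a8 and S100a9 predicts, and the lowest counting limit was 22.8 times. A counted tag outside the deleted part stays open, since the endothelial log2 ratio exceeded the median of the other 7 classes by only 0.30 and the deleted exons are not known. Exchanged library labels also stay open, because the lowest upper limit of the ratio over endothelial clusters, 1.29, decides only if the tag reports the deletion. An incomplete deletion may also leave Slc2a1 in place, and was not tested.

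The second pattern was that evening clock genes and immediate early genes stood higher in endothelial-like cells of the library labelled knockout. Morning clock genes there had a median of −0.02 (−0.19 to 0.13). The median of immediate early genes was above 0 in 8 of 8 classes, from 0.04 (−0.11 to 0.08) in lymphoid cells to 0.74 in endothelial-like cells. In neutrophil-like cells it was 0.14, below the median of 0.20 of random lists matched to the stress list. The stress list, which holds the immediate early genes, was lower within neutrophil-like clusters 0 and 2 and B-like cluster 1, at −0.47, −0.51 and −0.49. In neutrophil-like clusters 3 and 4 it was −0.04 and 0.46, so these clusters were split. A difference in clock phase at harvest is a candidate explanation that was not established. Evening genes exceeded morning genes in endothelial-like cells by 0.52 (0.32 to 0.75) on the log2 scale, just past the 0.5 set beforehand. The lower limit is under that size, and the pattern itself holds the evening genes, so this value largely restates it. The sign was the same in 6 of 8 classes, but only endothelial-like and neutrophil-like cells had an interval above 0. The neutrophil value rests on 2 evening genes, and lymphoid cells had −0.56 (−1.46 to −0.02). Glucocorticoid level stays open: the median of its genes, 0.19 (0.10 to 0.37), was below the size set beforehand and above 0 in 4 of 8 classes, which meets the bound set against it, but not beyond counting error, since 3 of the other 4 intervals include 0 and 1 lies below it. Stress of dissociation also stays open, since heat shock members had a median of −0.22 (−0.28 to −0.15) in endothelial-like cells but 0.10 (0.05 to 0.16) in macrophage-like cells. Hsph1 was lower and Cirbp higher in 8 of 8 classes, but other heat shock and cold-induced genes were less uniform, and no cause was tested. The genotype itself is confounded with the library and was not tested apart from it.

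The third pattern was the lower Spp1 in macrophage-like cells of the library labelled knockout. Spp1 was lower in other classes too, with log2 ratios of −3.18 in endothelial-like, −1.91 in monocyte-like, −1.74 in B-like, −1.48 in neutrophil-like and −1.05 in dendritic-like cells; carry-over between classes was measured for endothelial-like cells only. The makeup of the clusters is argued against as the whole cause, because within cluster 11, which holds most Spp1, the log2 ratio was −2.89 (−3.02 to −2.76). A few cells of very high Spp1 are argued against as the whole cause: in the library labelled wild type 64 cells, its top 5%, held 78.0% of Spp1, and without them it stood at 313 CPM against 117 CPM in all cells of the library labelled knockout, a log2 ratio of −1.41 (−1.54 to −1.28). Variation between animals and the genotype could each give such a difference, and 1 library per group cannot separate them.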

How the results depend on the processing

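The alternatives with equal cluster weights, with low-UMI endothelial clusters added and with other denominators of the macrophage share were chosen after seeing the data. The main results gave 112 alternative values within their counting interval, or within 1.5 times for counts, 32 that moved beyond it and 2 of opposite sign; the cause was not tested. Opposite sign is counted only where the main interval excludes 0, so the capillary difference of −2.01 points and macrophage cell cycle, at −0.11, are among the moved even where they turned sign; list medians are counted apart. With called doublets kept, Spp1 in endothelial-like cells was −1.71, endothelial glycolysis −0.0515, macrophage cell cycle −0.30, the capillary difference −7.43 points and the macrophage share 31.8% in the library labelled wild type and 12.1% in the library labelled knockout. With the stricter cell filter these shares were 22.5% and 8.12%, endothelial glycolysis −0.0375, resident genes 0.57, cell cycle −0.24 and the capillary difference 6.15 points. Without a cell filter the shares were 29.2% and 11.2%, cell cycle 0.0936, the capillary difference 3.87 points and the arterial difference −2.43 points, the opposite sign to the 4.62 reported. With genes scaled within each library the shares were 27.5% and 11.3%, resident genes 0.60 and the arterial difference −0.97 points, again of opposite sign. Leiden resolution 0.5 gave −6.81 points for capillary and 8.53 points for arterial cells. The macrophage share was 38.0% and 25.2% without neutrophil-like cells and 21.2% and 8.09% with unnamed immune clusters, where the denominator itself is the cause. Resident genes were 0.40 with TMM factors, 0.26 as a mean over cells, and 0.33 thinned to 2000 UMIs, where macrophage cell cycle was 0.0505. Equal cluster weights gave 0.0797 for Slc2a1, 0.0362 for resident genes, 0.0639 for the endothelial interferon list and 0.14 for macrophage MHC class II, the last 2 of opposite sign. Endothelial glycolysis was −0.0781 with low-UMI clusters added.

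The macrophage inflammatory list also took the opposite sign, at 0.0877 as a mean over cells, 0.0484 thinned and 0.12 with equal cluster weights. The other 24 list medians had 278 alternative values, 222 of them within the main interval; of the 15 medians whose interval excluded 0, 167 of 172 alternative values had the same direction. Ranges were 0.0797 to 0.64 for Slc2a1, −3.36 to −1.71 for endothelial Spp1, 0.21 to 0.48 for endothelial hypoxia, 0.48 to 0.76 for endothelial stress, −0.78 to −0.51 for lipid-associated, −0.61 to −0.38 for alternative activation and −0.46 to −0.19 for macrophage glycolysis. Lists in the outer 5% numbered 5 to 8 in endothelial-like and 6 to 10 in macrophage-like cells. Of the 24 ranked genes, 18 to 24 were shared in endothelial-like and 16 to 24 in macrophage-like cells. TMM factors, means over cells, thinning and the pseudocount give no value for shares of cells, and TMM factors and means over cells none for the thinned cell cycle share. No paired analysis was possible because each group was 1 library. Depth limits Spp1 in endothelial-like cells, at 10 UMIs in the library labelled knockout, and Arg1 in macrophage-like cells, at 8 UMIs.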

Other observations

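The tests and rankings in this part were chosen after seeing the data, and the directions are again between libraries as labelled. Monocyte-like cells of the library labelled knockout stood higher in Chil3, a chitinase-like lectin, by 2.501 (2.47 to 2.53) fold at 5254 CPM against 2101 CPM, in Ms4a8a by 2.44 (2.22 to 2.68) fold and in Fpr2, a formyl peptide receptor, by 2.38 (2.12 to 2.66) fold. In other classes the ratio of Chil3 was 2.75 in B-like, 2.33 in endothelial-like, 2.30 in stromal, 2.09 in neutrophil-like and 1.62 in macrophage-like cells, but 0.785 (0.689 to 0.893) in dendritic-like and 0.777 (0.582 to 1.03) in lymphoid cells. Chil3 was scarcer there than in monocyte-like cells, at 30.5 and 71.2 CPM in endothelial-like and 101 and 279 CPM in B-like cells (library labelled wild type first). Carry-over of monocyte RNA into other classes was not measured, so these ratios may not be their own expression. In monocyte-like cells the interferon-induced gene Ifi27l2a was 2.67-fold lower (2.59 to 2.74), Zbp1, a nucleic acid sensor, 2.19-fold (1.96 to 2.45), Ms4a4c 2.10-fold, Ms4a6d 2.00-fold and Fdps, of the cholesterol pathway, 1.96-fold. The interferon list had a median of −0.46 with 13 of 13 genes lower, and the cell cycle list −0.36 with 17 of 18 lower. Within clusters 5, 6 and 27 the interferon median was −0.48, −0.89 and −0.09 and the cell cycle median −0.26, −0.35 and 0.34, the last from 6 measured genes. Top2a and Pclaf of the cell cycle list are among the leading genes of cluster 5. That cluster was 7.41% of immune-like cells in the library labelled wild type and 5.01% in the library labelled knockout. The cell cycle median of the class can therefore also depend on its makeup. Dendritic-like cells stood higher in Ccl17 by 11.4 (10.5 to 12.5) fold, at 898.5 CPM against 78.7 CPM, and in Ccl22 by 4.98 (4.33 to 5.73) fold, both chemokines for the receptor CCR4. Cacna1a was higher there by 36.7 (22.2 to 65.2) fold and Alox15, a lipoxygenase, by 13.6 (9.09 to 21.2) fold. Ifitm1 was 18.1-fold lower (14.1 to 23.7), Ccl24 9.33-fold (6.25 to 14.5), Clec4n 5.01-fold (3.61 to 7.14), Cxcl10 4.82-fold (3.47 to 6.87) and Ptgs2 4.11-fold (3.15 to 5.46).

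Neutrophil-like cells of the library labelled knockout stood higher in Olr1, a receptor for oxidised lipoprotein, by 6.05 (5.56 to 6.60) fold and in Zeb2, a transcription factor, by 3.37 (3.20 to 3.55) fold. Stfa2 was higher by 3.75 fold, a value uncertain because of near-identical copies. Prok2, or prokineticin, was 5.35-fold lower (4.61 to 6.23), Ifi27l2a 3.57-fold and Wfdc17 3.09-fold. The interferon list had a median of −0.88 with 11 of 12 lower. Cluster 4 held most neutrophil-like cells of the library labelled wild type, 925 against 442, while clusters 0 and 2 held 1717 and 1112 in the library labelled knockout against 243 and 169. Within clusters 0, 2, 3 and 4 the interferon median was −0.11, −0.09, −0.43 and −0.25. In the 8 classes compared, Cirbp, which cold induces, had a ratio of 1.32 to 2.66 with an interval above 1 in 8 of 8, and the heat shock gene Hsph1 a ratio of 0.152 to 0.781 with an interval below 1 in 8 of 8. The lowest Hsph1 ratio, in neutrophil-like cells, rests on 18 and 5 UMIs. Rbm3, which cold also induces, had an interval above 1 in 6 classes and below 1 in 1, and the chaperone gene Hspa8 below 1 in 6 and above 1 in 2. Hsp90aa1 and Chordc1 had an interval below 1 in 4 classes each.

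Some unnamed clusters carried genes of developing blood cells and osteoclasts in both libraries. Cluster 17 held 150 cells in the library labelled wild type and 198 in the library labelled knockout and carried Elane, neutrophil elastase, at 12691 and 11517 CPM, with Mpo at 3531 and 4644 CPM. Clusters 13 and 19 carried the granule genes Camp and Ngp, with Camp at 43240.2 and 40748 CPM in cluster 13. Cluster 22, named B-like, carried the pre-B gene Vpreb3 at 2130.2 and 1555 CPM in 75 and 28 cells. Cluster 24, with 59 and 37 cells, carried Ctsk, or cathepsin K, at 5629 and 3964 CPM and Acp5, the tartrate-resistant phosphatase, at 3199 and 2591 CPM. Marrow or bone cells are not named in the labels, and their presence was not tested further, so the immune shares are not known to be those of muscle alone.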
